A study of Drosophila melanogaster with 13 samples.

How the data were processed

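The series holds 13 ChIP-seq samples of Drosophila melanogaster, 1 per group. In salivary glands of wandering larvae of OrR (a wild-type strain) and of a SuUR mutant, antibodies against gamma-H2Av were used, the phosphorylated form of the histone variant H2Av that marks DNA damage, with an input for each strain and a rabbit IgG control in OrR. In OrR egg chambers of stage 10 and of stages 12-13, 600 egg chambers per ChIP fixed in 2% formaldehyde, antibodies against SUUR (a chromatin protein of late replicating regions) and Cdc45 (a component of the replicative helicase) were used, with IgG and an input at each stage. Groups were taken from the sample labels. The 4 input samples have no peak list of their own and entered only through the authors' peak calls, so 9 peak lists were analysed.

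For all 4 egg chamber samples labelled SUUR or Cdc45, the run name in the header of the deposited list carries the other antibody than the label. Libraries are named here by their labels ("labelled SUUR", "labelled Cdc45"), and no direction between these antibodies can be read without this conflict in mind.

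Reads were mapped with BWA to dm3 (Release 5), per the submitters' processing notes. Peaks were called per library, not on pooled samples, per the file headers. The salivary gland lists came from MACS 1.4.2 with a p-value limit of 1e-05 and an effective genome size of 2.7e+09, far above that of a fly, per the file headers. They give the authors' tag counts per peak, a score that scales the −log10 of the p-value, a fold enrichment over the input and an FDR in percent, as deposited. The egg chamber lists came from MACS 2.0.10.20130419 with a p-value limit of 1e-03 and a genome size of 1.2e+08, per the file headers. They give the authors' pileup signal at the summit, −log10 p-values and fold enrichment over the input, as deposited. Their −log10 q-value column was not used, since the headers say q-values were not calculated. Scores and folds are the authors' own and served only to describe, rank or filter peaks within a list. Several lists shared an input: OrR gamma-H2Av and OrR IgG used the same one, and so did the 3 libraries of each egg chamber stage. Lists called against 1 input can overlap for that reason alone, so overlaps with IgG are given as the measured background. The SuUR list was called against its own input and has no IgG list here, so OrR IgG served for both strains. The caller's fragment length was 161 bp for OrR gamma-H2Av and 110 bp for SuUR, and between 36 and 58 bp in the egg chamber libraries, close to the 44 bp tags.

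Depth after duplicate removal, per the file headers, was 19208769 tags for OrR gamma-H2Av, 16337826 for OrR IgG and 15996251 for SuUR gamma-H2Av. At stage 10 it was 353742 for the library labelled SUUR, 8265341 for the one labelled Cdc45 and 3891175 for IgG. At stages 12-13 it was 4824942, 6942374 and 2592149 in the same order. The stage 10 library labelled SUUR is thus the shallowest, and 90.4% of its peaks had a summit pileup under 5 tags.

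A peak counted as shared when it overlapped a peak of the other list by 1 bp or more. The share was given with a Wilson 95% interval, which covers counting error only, and set against 1000 random circular shifts of 1 list along each chromosome, a permutation test with a two-sided p whose smallest value is 0.002. Such a p compares 2 lists, not conditions. Chromosome lengths were taken as the last peak end over the 9 lists. With 1 library per group no test between conditions was possible. The genome was also divided into windows of 100 kb. A window was called rich in gamma-H2Av when OrR peaks covered at least 20 percentage points more of it than OrR IgG peaks, and adjacent rich windows were merged into domains. The same limit over OrR IgG was applied to SuUR. The shares of rich windows that were also rich in SuUR were compared by Fisher's exact test over windows, which are not replicates and neighbour each other.

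The loci named were fixed before the data were examined: 6 follicle cell amplicons (DAFC-7F, 66D, 62D, 30B, 34B and 22B), the Bithorax and Antennapedia complexes and the histone cluster. Their Release 5 windows were written from general knowledge, rounded to 0.1 Mb, and are approximate. The rule also names the 10 domains with the largest difference between OrR gamma-H2Av and IgG, the 10 windows with the largest difference to IgG in each egg chamber ChIP, and the 5 peaks of highest fold in each list that overlap no IgG peak. Genes and bands outside these windows were left out, because the gene table used here is of Release 6 and peaks were not placed in genes. Locus percentiles rank the covered length among all windows of the same size on the 5 major arms (2L, 2R, 3L, 3R and X), in steps of 100 kb.

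Alternatives fixed before the data were examined were an overlap of 50% of the shorter peak, summits inside the other peak, the upper 50% of each list by p, equal numbers of peaks, the major arms alone, peaks shared with IgG left out, windows of 50 and 200 kb, limits of 10 and 40 points, widened locus windows and covered bp in place of peak numbers. Chosen after seeing the data were the antibodies named by the headers, a summit pileup of 5 tags or more for the shallow library, U and Uextra (unplaced sequence) left out, the bins of 5 or 10 kb inside loci, the windows rich in SuUR, the ranking of rich windows by the median fold of their OrR peaks, the limits of 10, 20 and 40% of arm windows covered, and the peak ranking on the major arms. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated lists 2993 of 2993 overlap calls equalled a brute-force count, a planted share of 30% was recovered as 30.2%, 2 of 100 independent pairs gave p under 0.05, and 30 of 30 planted windows were found. The simulated peaks were spread evenly at random over the major arms, without the clusters or unplaced sequence of the real lists. The planted windows were built above the limit. These checks therefore concern the code and do not show how the shift p behaves on clustered lists.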

Results

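ChIP-seq peak lists of 9 libraries were analysed, 1 library per group and with no replicates: gamma-H2Av in salivary glands of OrR and of the SuUR mutant, IgG in OrR salivary glands, and libraries labelled SUUR, labelled Cdc45 and IgG from egg chambers of stage 10 and of stages 12-13. Salivary gland lists held 5175 peaks for OrR gamma-H2Av, 5684 for OrR IgG and 6712 for SuUR gamma-H2Av, from 15996251 to 19208769 tags after duplicate removal. Stage 10 lists held 5147 peaks labelled SUUR, 24764 labelled Cdc45 and 5551 of IgG, from 353742, 8265341 and 3891175 tags. The lists of stages 12-13 held 9875, 13241 and 6933 peaks in the same order, from 4824942, 6942374 and 2592149 tags. Intervals are Wilson 95% intervals over peaks and cover counting error only. Coordinates are of Release 5 (dm3).

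The first comparison asked where gamma-H2Av lay in OrR salivary glands, a polytene tissue in which some late replicating regions stay underreplicated. Beyond IgG, gamma-H2Av peaks were gathered in wide blocks on the chromosome arms. The Bithorax complex (Ubx, abd-A and Abd-B, the homeotic genes of the posterior body) was among them: in its approximate window on 3R, 12400001 to 12900000, 25 gamma-H2Av peaks covered 109 kb, against 12.7 kb for IgG. The approximate window of the Antennapedia complex (lab, pb, Dfd, Scr and Antp, the homeotic genes of the anterior body) on 3R, 2.4 to 2.9 Mb, held no gamma-H2Av peak, and IgG covered 8.62 kb there. None of the 6 amplicon windows held a gamma-H2Av or IgG peak in salivary glands.

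Across the genome 44 windows of 100 kb were rich in gamma-H2Av, 34 of them on the major arms, and they formed 35 domains. The domain with the largest difference lay on X, 12.0 to 12.3 Mb, where gamma-H2Av covered 113 kb and IgG 16.3 kb. It was followed by 3L, 18.2 to 18.4 Mb, with 96.8 kb against 18.4 kb, and by 3R, 12500001 to 12700000, inside the Bithorax window, with 82.6 kb against 5.79 kb. Next came X, 20.5 to 20.8 Mb, X, 14.2 to 14.4 Mb, and 2L, 15.3 to 15.5 Mb, with 94.7, 71.6 and 70.7 kb of gamma-H2Av. The other 4 of the 10 named domains were 2RHet, 1.7 to 1.8 Mb, 3R, 23.9 to 24.0 Mb, 2L, 22.3 to 22.4 Mb, and 3R, 6.8 to 6.9 Mb, with 71.2, 60.8, 67.4 and 57.9 kb. In the rich arm windows the median coverage was 37.8% for gamma-H2Av and 5.76% for IgG. A gap of at least 20 points was required of these windows, so this contrast follows from their choice. Over all arm windows the mean coverage was 2.18% for gamma-H2Av and 1.60% for IgG.

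Peak by peak, gamma-H2Av and IgG overlapped widely. Of the 5175 OrR gamma-H2Av peaks, 52.4% (51.0 to 53.7%) overlapped an IgG peak, against 19.3% after shifts (two-sided permutation p = 0.002 by circular shifts, the smallest possible). On the major arms the share was 26.0% (22.8 to 29.4%) of 677 peaks, against 3.43% after shifts. Both lists used the same input. All 5 gamma-H2Av peaks of highest fold outside IgG peaks lay in U or Uextra, the unplaced sequence, with folds of 17.6 to 23.4.

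The second comparison asked whether gamma-H2Av occupancy depended on SuUR, the gene needed for underreplication in polytene cells. In the SuUR library the blocks on the arms were mostly missing, while peaks on the Het scaffolds, the assembled pericentric heterochromatin, covered more sequence in total. On the major arms gamma-H2Av peaks covered 2.60 Mb in OrR and 1.07 Mb in SuUR, with 677 and 205 peaks. OrR IgG covered 1.91 Mb of the arms, with 519 peaks, so SuUR lay below the OrR background there. Missing blocks can thus not be told apart from fewer arm peaks in the SuUR list as a whole. On the Het scaffolds gamma-H2Av peaks covered 1.35 Mb in OrR and 1.95 Mb in SuUR, with 1.15 Mb for OrR IgG. Most of this gain lay on 2RHet (537370 and 964940 bp) and 3LHet (430288 and 563993 bp), while 3RHet (268042 and 246342 bp) and XHet (43347 and 35370 bp) had less in SuUR. The Bithorax window held no SuUR peak, against 25 in OrR. On the whole of 3R the SuUR list held 3 peaks, against 61 for OrR gamma-H2Av and 45 for OrR IgG. Absence of SuUR peaks was therefore not particular to this window.

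Among the 34 rich arm windows, 1 was also rich in SuUR (2.94%, 0.521 to 14.9%), on 3L at 24.5 to 24.6 Mb, and 22 held no SuUR peak. The window at 24.5 Mb was the last, partial one of 3L, with coverage still counted over 100 kb. The nearby domain on 3L, 24.1 to 24.3 Mb, had 81.7 kb in OrR and 64.2 kb in SuUR. Its windows were not rich in SuUR, since IgG covered 34.3 kb there. Among the 10 rich windows elsewhere, 4 were also rich in SuUR (40%, 16.8 to 68.7%), 3 on 2RHet and 1 on 3LHet (two-sided Fisher's exact p = 0.00681 over windows). Each of the 10 held a SuUR peak. Over the whole genome, however, most windows elsewhere held a SuUR peak and most arm windows held none. Having a SuUR peak or none was therefore not particular to windows rich in OrR. The OrR peaks in the arm windows were weaker, with a median of the window's median fold of 4.43 against 5.24 elsewhere, and among the 22 windows of the higher fold, 1 of 13 and 4 of 9 stayed rich (Fisher's exact p = 0.116). Over all windows, 11 of 1194 on the arms (0.921%, 0.515 to 1.64%) and 35 of 503 elsewhere (6.96%, 5.05 to 9.52%) were rich in SuUR, so windows elsewhere were more often rich in SuUR whether or not they were rich in OrR. Of the 10 named domains, 3L at 18.2 Mb, 3R inside the Bithorax window, 3R at 23.9 Mb and 3R at 6.8 Mb had no SuUR peak. Those on 3R lie on an arm with 3 SuUR peaks in all, so absence there was not particular to them. The domain on 2RHet at 1.7 Mb kept its coverage, 71.2 kb in OrR and 74.1 kb in SuUR. The X domain at 12.0 Mb had 113 and 7.70 kb and the X domain at 14.2 Mb 71.6 and 2.71 kb. Coverage above IgG was kept in part at 2L, 15.3 Mb (70.7 and 22.9 kb, IgG 9.91 kb), and 2L, 22.3 Mb (67.4 and 20.3 kb, IgG 12.8 kb). At X, 20.5 Mb, gamma-H2Av covered 94.7 kb in OrR and 20.3 kb in SuUR, the latter below the 22.7 kb of IgG.

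The reverse was also seen. In all, 46 windows were rich in SuUR over OrR IgG, and 41 of them were not rich in OrR. Of the 41, 10 lay on the major arms, 17 on Het scaffolds, 1 on chromosome 4 and 13 in U or Uextra. Some of the 41 differed little from OrR and missed its limit through the subtraction of IgG. Coverage on 2LHet, 0 to 0.1 Mb, was 36.5% in SuUR and 30.3% in OrR, with 13.8% for IgG. Others differed more. On 2RHet, 1.9 to 2.0 Mb, coverage was 74.1% in SuUR and 5.11% in OrR. On chromosome 4, 1.2 to 1.3 Mb, it was 54.0% in SuUR with no peak in OrR. On 3LHet, 1.0 to 1.1 Mb, it was 54.5% against 9.01%. The arm windows of this kind included 2L, 17.7 to 17.8 Mb, with 48.0% against 6.01%, and 2R, 0.4 to 0.5 Mb, with 26.8% and no OrR peak. Several lay toward an arm end, such as 3L, 24.4 to 24.5 Mb, with 56.9% against 26.7%, and X, 22.2 to 22.3 Mb, with 20.9% and no OrR peak. The windows rich in SuUR were examined after the values were seen. Windows rich in either strain were chosen by their coverage in 1 library, so a shortfall in the other can follow from the choice.

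Single OrR peaks had a SuUR counterpart less often on the arms than elsewhere, while both shares lay above their shifts. Of the OrR peaks, 54.7% (53.4 to 56.1%) overlapped a SuUR peak, against 26.5% after shifts (two-sided permutation p = 0.002). On the major arms it was 16.8% (14.2 to 19.8%), against 1.78% after shifts, and outside them 60.4% (59.0 to 61.9%), against 30.2%, so relative to the shifts the arms stood higher (9.47 times against 2.00 times). Each strain was sampled once, so strain and library cannot be separated, and SuUR was set against OrR IgG. With windows of 200 kb or a limit of 40 points, 1 of 2 windows outside the arms stayed rich and none of the 13 and 8 arm windows did, and Fisher's exact test did not pass 0.05 (p = 0.133 and 0.200).

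**Figure D1:**
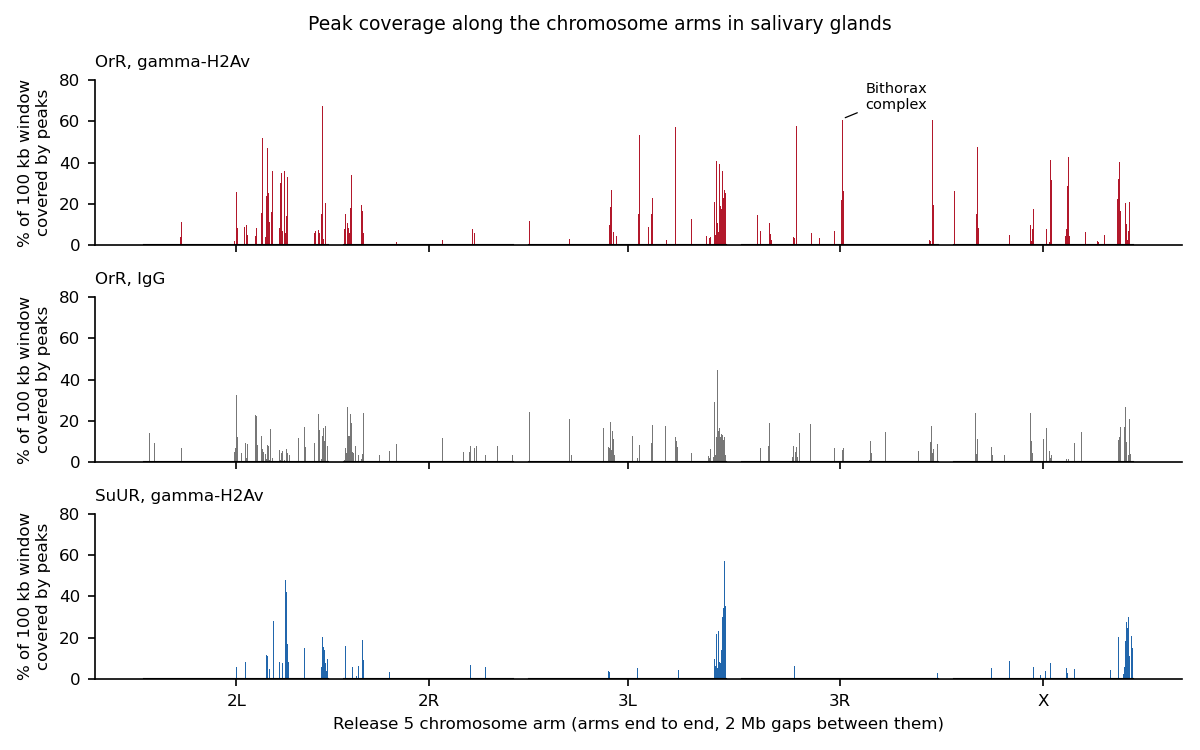
Percent of each 100 kb window covered by peaks along the 5 major arms (Release 5, arms end to end) in OrR gamma-H2Av (top), OrR IgG (middle) and SuUR gamma-H2Av (bottom), 1 library each. Blocks such as the Bithorax complex on 3R are seen in OrR and have no SuUR peak, while SuUR peaks lie mainly on 2L, 3L and X, those on X from 21.7 to 21.9 Mb in windows with little OrR coverage (2.36 and 6.89%). On the whole of 3R the SuUR list has 3 peaks, against 45 for OrR IgG.

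The egg chamber comparisons concerned SUUR and Cdc45 while follicle cells amplify the chorion gene regions. At the main amplicons origins fire up to stage 10 and forks move outward afterwards. In every such comparison the antibody in the file header is the other one than in the label. In the approximate window of DAFC-66D (Cp15, Cp16, Cp18 and Cp19, eggshell genes) on 3L, 8.6 to 8.9 Mb, the library labelled SUUR covered 35.3 kb at stage 10 and the library labelled Cdc45 5.18 kb, against 1.54 kb for IgG. At stages 12-13 they covered 131 and 71.3 kb, against 0.584 kb for IgG. In the window of DAFC-7F (Cp36 and Cp38, eggshell genes) on X, 8.3 to 8.6 Mb, they covered 3.93 and 2.08 kb at stage 10 and 44.2 and 21.8 kb at stages 12-13, against 0.076 and 0.082 kb for IgG.

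The covered region at DAFC-66D was wider at stages 12-13. At DAFC-66D, bins of 5 kb covered at least 50% ran from 8.705 to 8.740 Mb in the stage 10 library labelled SUUR, and no bin reached 50% in the one labelled Cdc45. At stages 12-13 they ran from 8.660 to 8.795 Mb in the library labelled SUUR and from 8.690 to 8.755 Mb in the one labelled Cdc45. The run labelled SUUR was broken at the bin 8785001 to 8790000, with 3.96% covered. At DAFC-7F at stages 12-13, coverage lay in a pair of blocks: 90.9% of 8.35 to 8.36 Mb and 82.2% of 8.39 to 8.40 Mb in the library labelled SUUR, with 1.98% of 8.37 to 8.38 Mb between them. At stage 10 the same bins held 9.68, 9.14 and 0.56% in that library, so the pair of blocks was present at lower coverage, in a library 13.64 times shallower. The library labelled Cdc45 had 45.7, 63.6 and 0.63% in the same bins at stages 12-13, and 0.43, 12.7 and 0% at stage 10, where no pair of blocks was seen. The bins were chosen after the values were seen.

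In the library labelled SUUR the other amplicons were covered less than DAFC-66D and DAFC-7F at both stages. At DAFC-34B (Vm34Ca, a vitelline membrane gene) on 2L, 13300001 to 13600000, the library labelled SUUR covered 1.801 kb at stage 10 and 18.3 kb at stages 12-13, and the one labelled Cdc45 5.34 and 8.06 kb, against 0.222 and 1.26 kb for IgG. Much of the coverage labelled Cdc45 lay in 1 bin, 13520001 to 13530000, with 47.6% and 43.2% covered, where IgG also had peaks (2.22% and 12.6%). At DAFC-22B on 2L, 1.8 to 2.1 Mb, the library labelled SUUR covered 0.823 and 8.95 kb, and the one labelled Cdc45 3.53 and 2.87 kb. All of the stage 10 coverage labelled Cdc45 at DAFC-22B lay in the bin at the edge of the window, 1800001 to 1810000. DAFC-62D (yellow-g and yellow-g2) and DAFC-30B stayed under 1.2 kb in all 6 lists. Of the 6 windows, 3 were in the top 5% of windows of their size in the stage 10 library labelled SUUR, none in the one labelled Cdc45 and 1 in IgG, and 4, 3 and 1 at stages 12-13. The stage 10 IgG list placed 6.42% of its arm coverage in the DAFC-66D window, so background at this amplicon was not absent at stage 10. The stage 10 library labelled SUUR had 353742 tags, so its extents are not comparable in depth with stages 12-13.

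**Figure D2:**
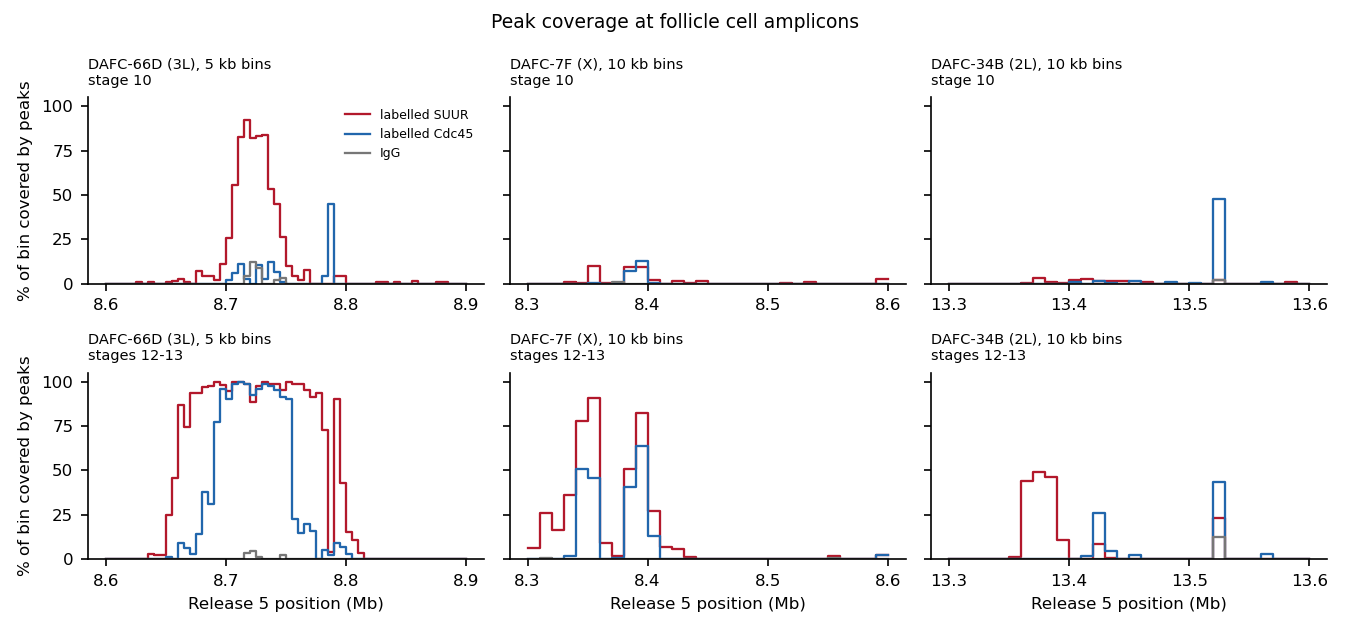
Percent of each bin covered by peaks at DAFC-66D, DAFC-7F and DAFC-34B (Release 5 positions) at stage 10 (top) and stages 12-13 (bottom), lines for the libraries labelled SUUR and Cdc45 and for IgG, 1 library each. At DAFC-66D the library labelled SUUR covers 35.3 kb at stage 10 and 131 kb at stages 12-13, where it has 13.64 times more tags, so depth and stage cannot be told apart. DAFC-7F has a pair of blocks at both stages in the library labelled SUUR, lower at stage 10.

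The libraries labelled SUUR and Cdc45 shared more peaks than shifted lists did at both stages. At stage 10, 17.6% (16.6 to 18.7%) of the peaks labelled SUUR overlapped a peak labelled Cdc45, against 2.98% after shifts, and 9.87% overlapped IgG. At stages 12-13, 38.7% (37.7 to 39.6%) of the peaks labelled SUUR did so, against 3.86%, and 30.3% overlapped IgG. Of the peaks labelled Cdc45, 3.58% overlapped a peak labelled SUUR at stage 10, against 0.621% after shifts, and 27.1% at stages 12-13, against 2.80%. On the major arms the shares of peaks labelled SUUR were 6.06% and 27.7%, against 1.03 and 0.954% after shifts. Every one of these permutation p by shifts was 0.002, the smallest possible. Both lists of a stage used 1 input. In the stage 10 list labelled SUUR, peaks with a pileup of 5 tags or more, a limit chosen after seeing the data, overlapped in 36.3%, while the share was 8.49% with equal numbers of peaks and 11.1% with peaks that overlap an IgG peak left out.

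Between stages, 16.2% (15.3 to 17.3%) of the stage 10 peaks labelled SUUR overlapped one of stages 12-13, against 1.36% after shifts, and 36.3% (35.7 to 36.9%) of those labelled Cdc45, against 3.90% (two-sided permutation p = 0.002 for each). Of the peaks labelled Cdc45 at stages 12-13, 67.4% had been seen at stage 10. IgG peaks of stage 10 overlapped those of stages 12-13 in 39.7%, against 3.40%, so recurrence was not particular to the ChIP lists. With equal numbers of peaks 47.8% of those labelled Cdc45 recurred. With peaks that overlap an IgG peak left out, the share labelled SUUR was 5.26%, and with a pileup of 5 tags or more it was 65.3%.

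The last comparison asked how peaks were spread over the chromosomes. Peaks labelled Cdc45 lay more often in heterochromatin than peaks labelled SUUR. Chromosome 4 and the Het scaffolds held 14.7% (14.3 to 15.1%) of the stage 10 peaks labelled Cdc45, 8.04% (7.33 to 8.82%) of those labelled SUUR and 1.42% of IgG. At stages 12-13 they held 14.8% (14.2 to 15.4%), 3.58% (3.24 to 3.97%) and 3.16%. The windows of 100 kb with the largest difference to IgG labelled Cdc45 at stage 10 were 2RHet, 3.2 to 3.3 Mb, and chromosome 4, 0 to 0.1 Mb, with 24.0 and 23.3% covered, and 7 of the top 10 were on chromosome 4 or Het scaffolds. In the libraries labelled SUUR the first window was 3L, 8.7 to 8.8 Mb, inside DAFC-66D, with 33.1% at stage 10 and 88.0% at stages 12-13. The same window was first in the library labelled Cdc45 at stages 12-13, with 57.3%. Of its top 10 windows 6 lay on the major arms and 4 on chromosome 4 or Het scaffolds. Those on the arms were 3L, 8.6 to 8.7 and 8.7 to 8.8 Mb, and X, 8.3 to 8.4 Mb, inside amplicon windows. The others were 3L, 23.5 to 23.6 and 23.9 to 24.0 Mb, and 2L, 22.2 to 22.3 Mb, toward the high-coordinate end of these arms. The histone cluster, a repeated gene array on 2L at 21400001 to 21600000, gave 43.6 kb labelled SUUR, 5.27 kb labelled Cdc45 and 4.69 kb of IgG at stages 12-13. These directions carry the label conflict.

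**Figure D3:**
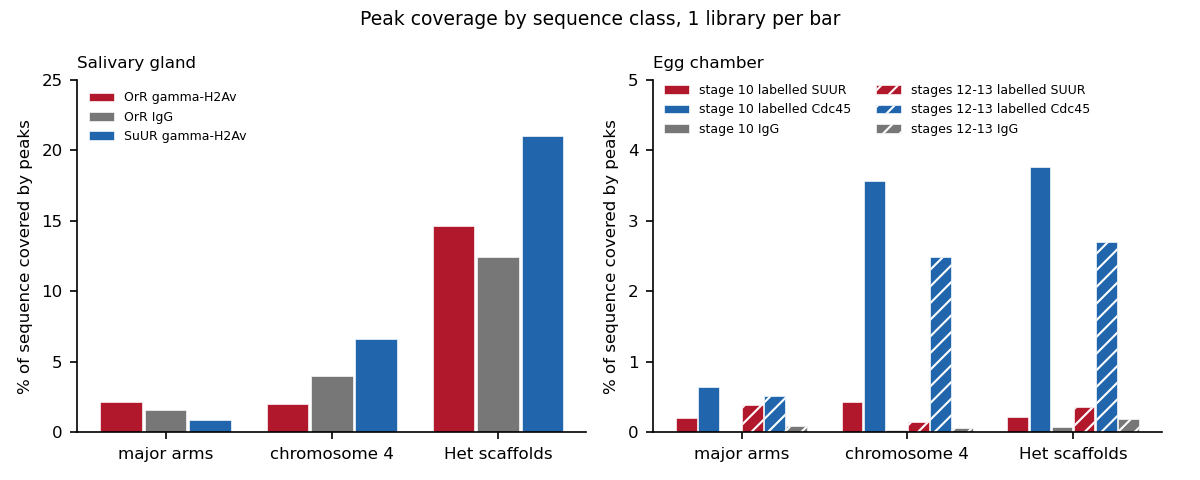
Percent of the major arms, chromosome 4 and the Het scaffolds covered by peaks in salivary glands (left) and egg chambers (right), 1 library per bar, hatched for stages 12-13. SuUR gamma-H2Av covers 21.0% of the Het scaffolds and 0.903% of the arms, against 14.6 and 2.19% in OrR.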

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

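Of the tests in this part, those of all 3 patterns were chosen, and their limits set, after the values were seen, and no pattern has a replicate.

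The antibody in the headers differs from the label in all 4 egg chamber samples labelled SUUR or Cdc45. If the labels were exchanged, the library labelled Cdc45 should lie more in chromosome 4 and the Het scaffolds, where the SUUR protein is known to bind. In lists of equal length the share was 10.7% labelled Cdc45 and 8.04% labelled SUUR at stage 10, a ratio of 1.33, and 14.0% against 3.58% at stages 12-13, a ratio of 3.91. The library labelled SUUR was the shallower at both stages, 23.4 times at stage 10 and 1.44 times at stages 12-13, and the effect of depth on the share cannot be told apart from that of the antibody, since chance peaks of a shallow list can move the share either way. Exchanged labels may account for the header names, as a hypothesis that rests on background knowledge of SUUR binding, and wrong names in the headers are not excluded.

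Arm windows rich in gamma-H2Av in OrR, the Bithorax complex among them, were rarely rich in SuUR. They were chosen by their OrR coverage, so another library can fall short in them through this choice alone. In the reverse direction, 10 of the 11 arm windows rich in SuUR were not rich in OrR. The Bithorax complex lies on 3R, where the SuUR list held 3 peaks in all. Lower sensitivity of the SuUR library would remove the weaker signal first, which is that of the arms, and among windows of the higher OrR fold 1 of 13 on the arms and 4 of 9 elsewhere stayed rich (two-sided Fisher's exact p = 0.116), so it stays open, and 35 of 503 windows elsewhere against 11 of 1194 on the arms were rich in SuUR in any case. Low input at underreplicated DNA would raise IgG too: arm windows covered at least 10, 20 and 40% numbered 81, 48 and 16 for gamma-H2Av and 78, 18 and 1 for IgG, a smallest ratio of 1.04, and mean arm coverage differed 1.36 times. IgG was itself raised in the rich arm windows, with a median of 5.76% against an arm mean of 1.60%, so a contribution of low input stays open. That this gamma-H2Av may depend on SuUR, as the design asks, is a hypothesis, since other differences between the strains, or between 2 single libraries, were not tested.

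At DAFC-66D the covered region was wider at stages 12-13 than at stage 10. At stages 12-13 IgG placed 0.513% of its arm coverage in the window, against 28.3% labelled SUUR and 11.7% labelled Cdc45. At stage 10 the IgG share was 6.42%, against 14.9% labelled SUUR and 0.679% labelled Cdc45. Each list was called against the input of its stage, in which amplified DNA is also raised, so IgG need not gain peaks with copy number. These shares therefore cannot decide whether copy number widened the coverage, and it stays open at both stages. For the library labelled Cdc45 depth fell to 0.840 of its stage 10 value while coverage rose 13.7 times, or 24.2 times without the single bin, 8785001 to 8790000, that held 43.2% of its stage 10 coverage, which argues against depth. For the library labelled SUUR depth rose 13.64 times, so depth and stage cannot be told apart. Outward movement of forks may account for the widening, as a hypothesis that was not tested. The centre was not vacated: at stages 12-13 each bin of 8.705 to 8.740 Mb was covered at least 75% in both libraries. The library labelled Cdc45 had no bin covered 50% at stage 10, so it gained a block there.

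The remaining results were noted because the sign of a difference turned between stages or strains, and none of these differences was tested. Differences between the labelled libraries are in kb, not adjusted for depth. The library labelled SUUR was 23.4 times shallower at stage 10 and 1.44 times at stages 12-13. A turn between stages can thus not be told apart from depth. At DAFC-34B the library labelled SUUR minus the one labelled Cdc45 was -3.54 kb at stage 10 and 10.3 kb at stages 12-13. At DAFC-22B it was -2.71 and 6.09 kb, and at both loci most of the stage 10 coverage labelled Cdc45 lay in 1 bin of 10 kb. At the Antennapedia complex it was 0.451 and -0.061 kb, a few peaks in all. At the histone cluster it was -7.48 and 38.3 kb. At stages 12-13 the cluster stood at percentile 99.7 of windows of its size in both the library labelled SUUR and IgG. At the Bithorax complex gamma-H2Av minus OrR IgG was 96.0 kb in OrR and -12.7 kb in SuUR. At the histone cluster it was -0.022 kb in OrR and 2.19 kb in SuUR.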

How the results depend on the processing

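No paired analysis was possible because each group has 1 library. Of 41 alternatives of the 6 overlap results, 4 (the headers' antibodies, chosen after seeing the data) only exchange list names. For the overlap of peaks labelled SUUR and Cdc45 this exchange turns the direction, and the share was 3.58% at stage 10 and 27.1% at stages 12-13. The other 37 stayed above their shifts, all at the smallest p the shifts can give, which therefore cannot rank them. Their shares ran from 26.0 to 50.8% for OrR gamma-H2Av with IgG, 16.8 to 52.2% with SuUR, 6.06 to 36.3% at stage 10, 27.7 to 33.5% at stages 12-13, 5.26 to 65.3% labelled SUUR between stages and 26.5 to 47.8% labelled Cdc45, the 36.3 and 65.3% from a pileup of 5 tags or more, chosen after seeing the data. Of 49 alternatives of window, amplicon and chromosome values, 22 stayed within the limits set for them. The number of gamma-H2Av-rich windows, 44, was 94 with windows of 50 kb, 15 with 200 kb, 92 at 10 points, 10 at 40 points and 26 in the upper 50% of each list. Those also rich in SuUR, 5, were 20, 1, 32, 1 and 3 in the same order and 1 on the major arms alone. Split by place, the arm share also rich in SuUR was 5 of 65, 0 of 13, 8 of 52, 0 of 8 and 0 of 20, and elsewhere 15 of 29, 1 of 2, 24 of 40, 1 of 2 and 3 of 6. The IgG amplicon windows in the top 5% were 2 at stage 10 in the upper 50% of the list and 0 at stages 12-13 with widened windows, against 1 in each. The percent of peaks on the major arms in the upper 50% of the list was 6.33 for OrR IgG, 59.7 for stage 10 labelled SUUR, 22.05 for labelled Cdc45, 2.13 for IgG, and 31.1, 28.4 and 14.4 at stages 12-13. By covered bp it was 30.4 for OrR gamma-H2Av, 28.3 for OrR IgG, 11.6 for SuUR, 26.4 for stage 10 labelled Cdc45, 3.95 for IgG, 39.7 for stages 12-13 labelled SUUR and 17.3 for IgG. The cause of these moves was not tested. Depth limits the stage 10 library labelled SUUR most, with a median pileup of 3 tags.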

Other observations

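The hypothesis that egg chamber peaks labelled Cdc45 at stage 10 concentrate in the arm windows rich in gamma-H2Av in salivary glands was written before its result was seen. Of 6926 arm summits, 7.91% (7.30 to 8.57%) lay in these windows, against 3.01% after shifts (two-sided permutation p = 0.0160), which met the limit set. Over the 6 egg chamber lists the Benjamini-Hochberg adjusted p was 0.0779, so the result fails the correction and stays open. At stages 12-13 the list labelled Cdc45 gave 7.82% against 3.04% (permutation p = 0.0260, adjusted p = 0.0779). The lists labelled SUUR gave 2.75% and 2.14%, and IgG 6.83% at stage 10, with 17 of 249 summits, and 2.81% at stages 12-13.

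Among peaks ranked by fold, in the ChIP lists only those that overlap no IgG peak, most of the highest fell in unplaced sequence: of the 5 highest in each of the 9 lists, 39 of 45 lay in U or Uextra. The exceptions were all in the libraries labelled SUUR. At stage 10 they were 3L, 22804469 to 22805020, with a fold of 41.9, X, 19291853 to 19291915, with 17.3, and 3R, 19939955 to 19940017, with 13.57. At stages 12-13 they were 3R, 19519866 to 19520295, with 9.96, X, 8644666 to 8644743, with 9.705, and 2L, 1301958 to 1302221, with 9.404. None of these 6 lies in a named window.

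On Het scaffolds and chromosome 4, SuUR coverage exceeded OrR coverage by 20 points or more in 18 of 110 windows and the opposite held in 8. On the major arms the numbers were 9 and 33 of 1194 windows. These counts were chosen after the values were seen and were not tested.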
